A study of Saccharomyces cerevisiae with 21 samples.

How the data were processed

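RNA was sequenced from 21 libraries of the budding yeast Saccharomyces cerevisiae, 1 for each time point from 0 to 200 min in steps of 10 min. All came from cells labelled as the clb1-6 mutant, in which the genes of the 6 B-type cyclins carry disruptions and a CLB1 copy is driven by the galactose-inducible GAL1 promoter. Per the labels, MATa bar1 cells were held in G1 with the mating pheromone alpha-factor (30 ng/ml for 160 min) and released at 30 °C from galactose medium into dextrose medium. There were no replicates at any time point, and none of the 210 pairs of libraries held identical values.

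Libraries were made with a stranded mRNA kit. The submitters named STAR, Cufflinks, Cuffnorm and genome build R64, with no versions given in the sources used here. The deposited values are FPKM (fragments scaled by transcript length and library size) as Cuffnorm scales them across libraries, with 1 added to every value by the authors. The unit was inferred from the values: no value was under 1 and library sums differed, unlike those of transcripts scaled to a fixed total. The added 1 was subtracted, so every FPKM given here is on the scale before that addition, and a gene at 0 is one listed at 1 in the table. A table of 50 wild-type columns belongs to another series and was not used here, so no comparison with wild-type cells was made.

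The table held 7126 genes and other loci, of which 528 were at 0 in all 21 libraries. Names were matched without regard to case to the R64 annotation, which gave locations and lengths for 6208 of them (87.1%). Read counts are not given in the sources used here. A step of 1 fragment was sought in genes over 1000 bp, only where FPKM times length in bp lay between 30 and 80. In that window 1 to 12 genes per library had a median of 0.0445 (70 min) to 0.0656 FPKM (60 min) for 1000 bp. The window bounds this median, so any library would have given a value within it. If that median is 1 fragment, a gene of that length at 1 FPKM rested on about 15.2 to 22.5 fragments. This is an approximation from few genes that gives no counting interval. The sum of FPKM ran from 1212671 at 180 min to 1911174 at 0 min, and 680 to 822 loci were at 0 per library (median 748). The 10 most abundant loci took 10.5% to 19.2% of the sum. Among the genes of the lists, CLB4 and MF(ALPHA)1 fell under the minimum of every fit, HXT6 under that of the oscillation and window fits, MLS1 and POT1 under that of the oscillation fit alone, and FKS2 was not in the table.

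Values were analysed as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, with moderated variances and a mean-variance trend, and the Benjamini-Hochberg adjustment at 0.05. Genes needed a mean FPKM of at least 1 over the libraries of each fit. Change over time was tested with a natural cubic spline of 6 degrees of freedom over all 21 libraries (6198 loci), and a gene was called at a fitted range of at least 1 on the log2 scale. Repeated oscillation was tested as a cosine and a sine added to a linear and quadratic trend from 20 min on (6194 loci), at the period between 50 and 130 min, in steps of 5 min, that explained most variance in the 7 cell-cycle lists. Periodic calls needed a peak-to-trough amplitude of at least 1. A change of the oscillation was tested by adding products of cosine and sine with time. The late window (110 to 200 min, 10 libraries) was compared with the early window (10 to 100 min, 10 libraries) over 6194 loci. Neighbouring time points of 1 culture are not independent replicates, so p-values from these fits are too small.

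Gene lists were compared between the windows with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, each adjusted over the 29 lists. Periodic calls per list were compared with those of all other genes by a two-sided Fisher's exact test. The 0 min library was compared with the mean of 20, 30 and 40 min without a test between libraries, and each list's median was ranked among 10000 random lists of the same size matched on mean expression. Times of the highest value up to 100 min were compared between lists by a two-sided permutation test across genes with 100000 resamples, chosen after the data were seen because the planned test on fitted peaks needed more periodic genes than most lists had. Genes are not independent replicates in any of these tests across genes.

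The 29 lists, the tests, the thresholds, the rule for named genes and most alternatives were fixed before the data were examined. The rule named all genes of the deleted and the marker list. In each comparison it named up to 4 members per list with the largest effect past the threshold, or up to 2 as values where none passed. Over all loci it named the 10 largest in each direction or kind. Lists with more than 4 such members are described by a choice among them. Many loci named by the last part were under 300 bp or had no annotated length, so the same ranking was repeated among genes of at least 300 bp, a step chosen after the data were seen.

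The fits were tested on simulated data over 6198 loci, with 200 changed genes. Values were drawn independently around each gene's mean with its residual SD. Recovery was counted at adjusted p under 0.05 alone, and oscillations were fitted at their true period. Recovery under the minimum range or amplitude of the calls was therefore not measured. With a simulated size of 1 on the log2 scale, 73.0% were recovered for change over time, 83.5% for an oscillation of 75 min, 85.0% for one of 100 min, 52.5% for a fading oscillation and 93.5% between the windows. At a size of 2 these were 92.0%, 96.0%, 95.5%, 82.0% and 97.5%, and the grid returned the true period of 75 or 100 min. Between 5 and 14 of the 5998 unchanged genes were called. The simulated time points were independent, so these counts give no rate of false calls for the linked libraries of this course. Alternatives covered the pseudocount, the low-value filter, the scaling between libraries, the variance prior, each library left out in turn, the spline, the period, the trend, the time points and the windows. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 handled the tables, and matplotlib 3.10.9 drew the figures.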

Results

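The series follows gene expression after release from G1 arrest in yeast whose B-type cyclin genes CLB1 to CLB6 are disrupted. It holds 21 mRNA libraries from 0 to 200 min, 1 every 10 min, with no replicates, so single time points carry no error of their own. Values are FPKM as deposited by the authors, with the added 1 removed. Sums of FPKM ran from 1212671 to 1911174 per library, and read counts are not given in the sources used here. The spread of the change from 1 time point to the next (SD of log2 differences over genes) was largest from 10 to 20 min, at 0.768, and smallest from 150 to 160 min, at 0.355. The pheromone was removed and galactose was replaced by dextrose at the same moment, so responses to both changes start together.

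The first question is what the altered genes themselves showed. CLB6 (YGR109C, chromosome VII, 705359 to 706501), an S-phase cyclin gene, went from 1.84 FPKM at 0 min to 156 at 20 min and 160 at 30 min, was at 4.79 by 80 min and reached 52.7 at 200 min. CLB5 (YPR120C, chromosome XVI, 773875 to 775182), its partner in S phase, went from 22.2 at 0 min to 80.4 at 20 min and was at 49.5 at 200 min. CLB1 (YGR108W, chromosome VII, 703636 to 705051), the mitotic cyclin gene supplied on the GAL1 promoter, declined from 293 to 90.4, and CLB2 (YPR119W, chromosome XVI, 771653 to 773128) went from 38.1 to 93.3 at 60 min and 69.8 at 200 min. All 4 changed over time (limma, adjusted p = 1.11e-05 for CLB6, 0.00150 for CLB5, 4.69e-10 for CLB1 and 1.08e-05 for CLB2), though CLB5 did not pass without the 0 min library (adjusted p = 0.246) or with a spline of 4 degrees of freedom (0.113). CLB3 (YDL155W, chromosome IV, 176773 to 178056) stayed between 20.1 and 32.2 FPKM with a fitted range of 0.42, and CLB4 (YLR210W, chromosome XII, 562008 to 563390) was listed at 0 in every library. BAR1, which encodes the protease that degrades alpha-factor, lay between 1.34 and 3.18. Each of the 6 cyclin genes has 1 coding exon in build R64, and a value per gene does not show which part of a disrupted locus the reads came from.

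Markers used to disrupt these genes were expressed throughout. LEU2 (leucine synthesis) went from 298 FPKM at 0 min to 66.2 at 40 min and 92.1 at 200 min, TRP1 (tryptophan synthesis) from 413 to 149 and 176, and URA3 (pyrimidine synthesis) from 255 to 155 and 106. ARG4 (arginine synthesis) went from 791 to 202 at 40 min and back to 758 at 200 min. ADE1 was at 129 at 0 min and 213 at 200 min, and HIS2 was at 99.3 and 104. Of these 6 genes 5 changed over time by the limma test with a fitted range of at least 1, and HIS2, with a range of 0.82, did not reach that range. Without the 0 and 10 min libraries LEU2 (adjusted p = 0.391) and TRP1 (0.847) did not pass.

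**Figure D1:**
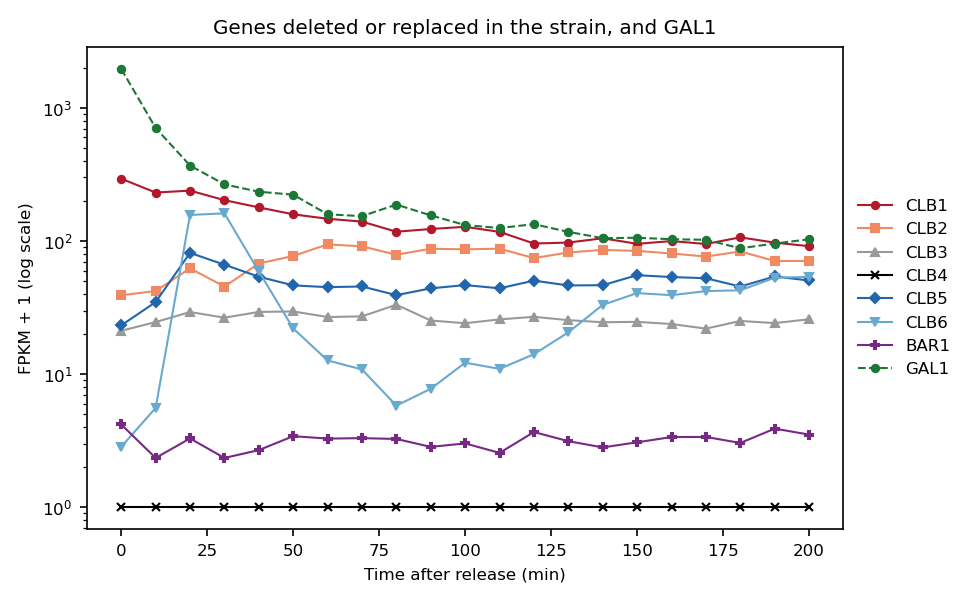
FPKM + 1 on a log axis against time after release in min for the 6 cyclin genes, BAR1 and GAL1, each point 1 library. CLB6 went from 1.84 FPKM at 0 min to 160 at 30 min and 4.79 at 80 min, while CLB4 was at 0 throughout.

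The early libraries address the release from pheromone and the move from galactose to dextrose, which cannot be separated here. Between 0 min and the mean of 20 to 40 min, mating genes were lower. GAL1 (YBR020W, chromosome II, 279021 to 280607), the galactokinase gene, went from 1962 FPKM at 0 min to 368 at 20 min and 234 at 40 min, and FUS1 (YCL027W, chromosome III, 71803 to 73341), needed for cell fusion in mating, from 333 to 121 and 88.3. The pheromone list had a median log2 difference of -1.93, with 25 of 26 members at least 2-fold lower, among them ASG7 (-3.09), FIG2 (-2.99), AGA1 (-2.92) and FUS3 (-2.65). Galactose genes had a median of -2.26, with 8 of 8 at least 2-fold lower, including GAL1 (-2.79), GAL2 (-2.43), PGM2 (-2.42) and GAL7 (-2.32). Both medians stood at percentile 0 of the matched random lists.

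Genes of carbon use and storage were lower in the same interval. Glycolysis had a median of -2.06, with 15 of 16 members at least 2-fold lower, among them the enolase gene ENO1 (-4.74, from 2525 FPKM at 0 min to 186 at 20 min), TDH1 (-3.68), TDH2 (-2.88) and PGK1 (-2.43). Stress genes under Msn2/4 had a median of -2.59 (20 of 22 at least 2-fold lower), including the cell-wall protein gene SPI1 (-4.42), GPH1 (-3.49), GAD1 (-3.31) and TSL1 (-3.30). Glucose-repressed genes had a median of -1.69, with 18 of 21 at least 2-fold lower, such as the hexose transporter HXT7 (-4.26) and the kinases GLK1 (-4.03) and HXK1 (-3.91). TCA cycle genes stood at -1.24, led by SDH4 (-1.79) and SDH1 (-1.70), and cell wall integrity genes at -2.09, led by PST1 (-2.98) and CWP1 (-2.25). Percentiles were 0 for the first 4 of these 5 lists and 0.01 for cell wall integrity. Hexose transporter genes of the glucose-induced list were lower as well, HXT4 by -2.17 and HXT1 by -1.26, and that list's median was -0.79 (percentile 3.07).

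Genes of the G1/S transition were higher in that interval. The SBF list (budding and G1 cyclin genes under the factor SBF) had a median of +2.44, with 14 of 19 members at least 2-fold higher, including PCL1 (+4.57), CLN1 (+4.30), YOX1 (+3.79) and CSI2 (+3.41). DNA replication genes under MBF had a median of +2.18, with 28 of 32 at least 2-fold higher, among them the ribonucleotide reductase gene RNR1 (YER070W, chromosome V, 298950 to 301616; +4.74, from 21.5 to 1085 FPKM at 20 min), the cohesin gene MCD1 (+4.61), TOS4 (+4.32) and NRM1 (+4.22). All 9 histone genes were at least 2-fold higher (median +2.10), with HTB2 at +4.44 and HTA2 at +4.29, and the Hcm1 targets had a median of +1.45, with SPC98 at +2.92 and ESP1 at +2.16. Ribosome biogenesis genes stood at +0.75, with 26 of 26 higher, led by RRP12 (+1.30) and RRP9 (+1.24). These 5 medians were at percentile 100.

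Other lists moved less or in both directions between those times. Medians were -0.39 for the ECB and MCM list, with SWI4 at +2.40 and FAR1 at -1.68, and 0.00 for the Clb2 cluster, with DBF2 at -1.67 and BUD3 at +1.39. Respiratory chain genes stood at -0.37, ribosomal proteins at -0.33, ergosterol genes at -0.43, DNA damage genes at -0.57, Hsf1 chaperones at -0.21 and Gcn4 targets at -0.26. Sulfur genes stood at +0.45, phosphate genes at +0.31 and iron genes at +0.37, with HMX1 at -2.40 and SIT1 at +1.83. Markers of MAT alpha cells had a median of -0.03 and meiosis genes of -0.21. With only 1 library at 0 min there is no test of these differences. Rescaling each library to one sum of FPKM turned the MAT alpha median to 0.14 and that of the Clb2 cluster to 0.18, and left the sign of every other list median as it was.

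Over all loci, the rule named for the largest falls YLR149C-A, YMR242W-A, YMR013C-A, YGR068W-A, YBR141W-A, YBR126W-B, YBL006W-A, YOR161W-A, ENO1 and YBR221W-A. For the largest rises it named YJL136W-A, YPL152W-A, YKL100W-A, YDR524C-A, YGR204C-A, TOS6, CLB6, YMR013W-A, snR79 and RNR1. All but ENO1, TOS6, CLB6 and RNR1 were under 300 bp or without an annotated length. Among genes of at least 300 bp, the lowest values against 0 min after ENO1, SPI1 and HXT7 belonged to the glycogen branching enzyme gene GLC3 (-4.21), the pyruvate kinase gene PYK2 (-4.15), GLK1, HXK1, EMI2 (-3.86), the glycogen synthase gene GSY1 (-3.85) and HSP30 (-3.76). TOS6, a cell-wall protein gene, went from 88.0 FPKM at 0 min to 3180 at 20 min (+5.35 for 20 to 40 min), and SPO16 stood at +4.34.

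**Figure D2:**
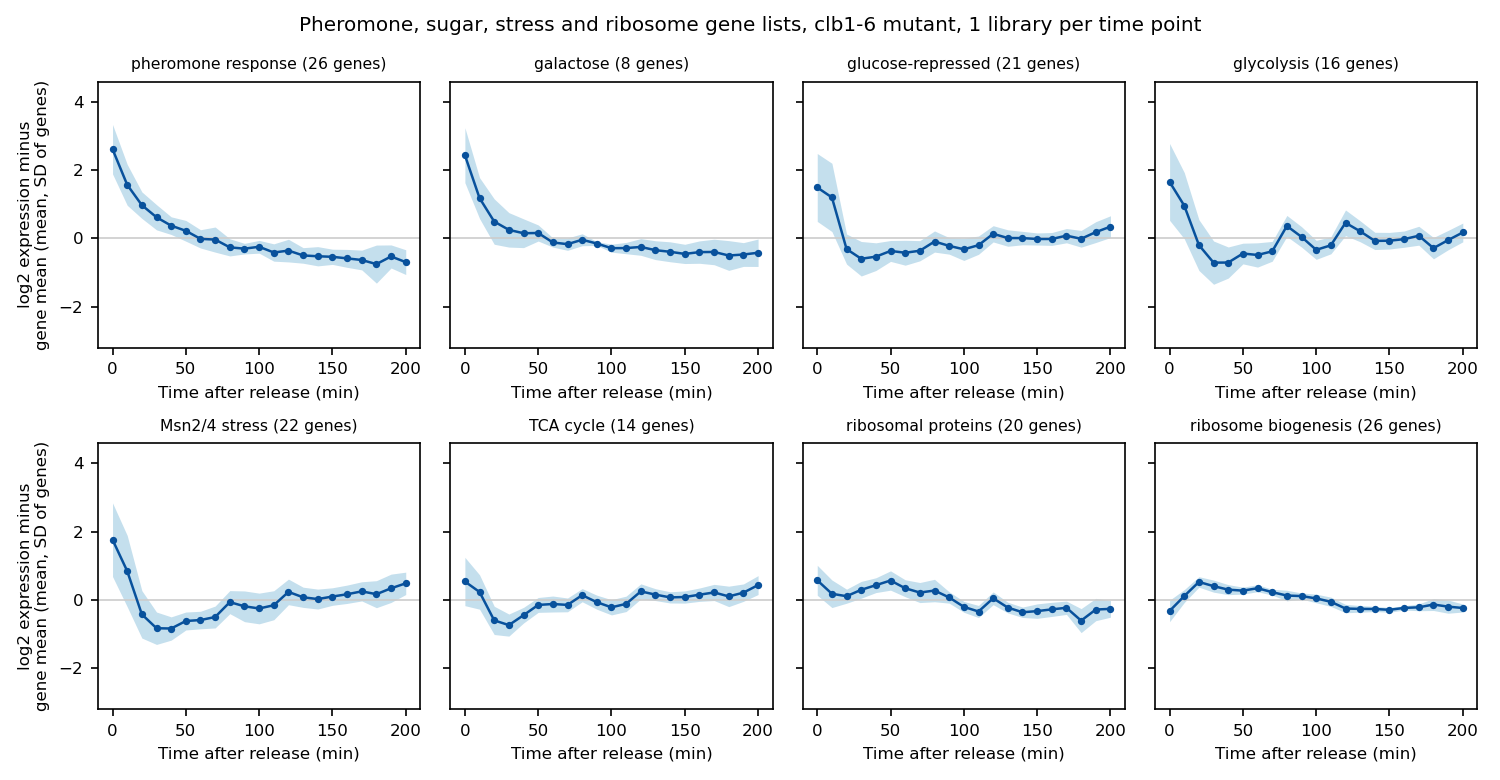
Mean log2 expression of each list relative to its genes' means (line, 1 point per library) and SD over genes (band) against time in min, for pheromone, sugar, stress and ribosome lists. Pheromone and galactose genes were highest at 0 min and ribosome biogenesis genes at 20 min.

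Change over the whole course was the rule for most genes. By limma, 5127 of 6198 loci passed adjusted p under 0.05, and 2775 of them also had a fitted range of at least 1. Their fitted values were highest at 0 or 10 min for 1218 loci, at 20 to 50 min for 699, at 60 to 150 min for 251 and at 160 min or later for 607. From 0 to 200 min the fitted curve rose for 1298 and fell for 1477. Without the 0 and 10 min libraries 1734 were called, and without the 0 min library alone 1910, so many of the calls depend on the first time points.

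The cell-cycle lists changed as follows. MBF genes rose and fell early, with 30 of 32 called (PRI1 and CTF4 not). RNR1 was at 97.4 FPKM at 70 min and 476 at 200 min, and the replication clamp gene POL30 (YBR088C, chromosome II, 424990 to 425766) went from 71.3 at 0 min to 1380 at 20 min, 101 at 80 min and 502 at 200 min. MCD1 went from 4.66 to 217 at 20 min, 38.4 at 70 min and 104 at 200 min. The list mean stood at -1.42 at 0 min, 1.49 at 20 min, -0.59 at 70 min and 0.28 at 200 min, on the log2 scale relative to each gene's mean. SBF genes had 18 of 19 called (YOX1 not, adjusted p = 0.120, but 0.00642 without the 0 min library and 0.0165 without 10 min), with a list mean of -1.80 at 0 min, 0.53 at 20 min, -0.27 at 70 min and 0.46 at 200 min. The G1 cyclin gene CLN1 went from 8.92 to 243 FPKM at 20 min and was at 146 at 200 min (adjusted p = 0.107 without the 0 min library), and PCL1 from 6.89 to 229 at 20 min and 363 at 200 min. SVS1 and SRL1, which encode cell-wall proteins, reached 1741 and 1837 at 200 min from 150 and 155.

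All 9 histone genes changed. HHF1, encoding histone H4, rose from 226 FPKM at 10 min to 7648 at 50 min and stood at 4646 at 110 min and 7358 at 200 min. HTA2, HTB2 and HHF2 rose over the same interval to 4112, 5724 and 7383 at 40 min, and the list mean went from -2.69 at 0 min to 0.56 at 50 min and 0.64 at 200 min. Hcm1 targets had 9 of 12 called, with the spindle pole gene SPC98 going from 8.77 FPKM to 88.1 at 30 min and the separase gene ESP1 from 6.84 to 40.1 at 40 min. Of the Clb2 cluster, genes of G2 and mitosis, 14 of 20 were called. In that list SUR7 went from 24.5 FPKM to 236 at 80 min and BUD3 from 7.21 to 38.4 at 110 min, while the kinase gene DBF2 went down from 73.6 to 17.7 at 200 min. The ECB and MCM list had 8 of 10 called. MCM7, MCM5 and MCM3, subunits of the replicative helicase, peaked at 10 min with 54.8, 60.0 and 51.2 FPKM and stood at 6.99, 13.5 and 8.92 at 200 min. FAR1, the inhibitor of G1 cyclin kinase, went down from 210 to 17.2.

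**Figure D3:**
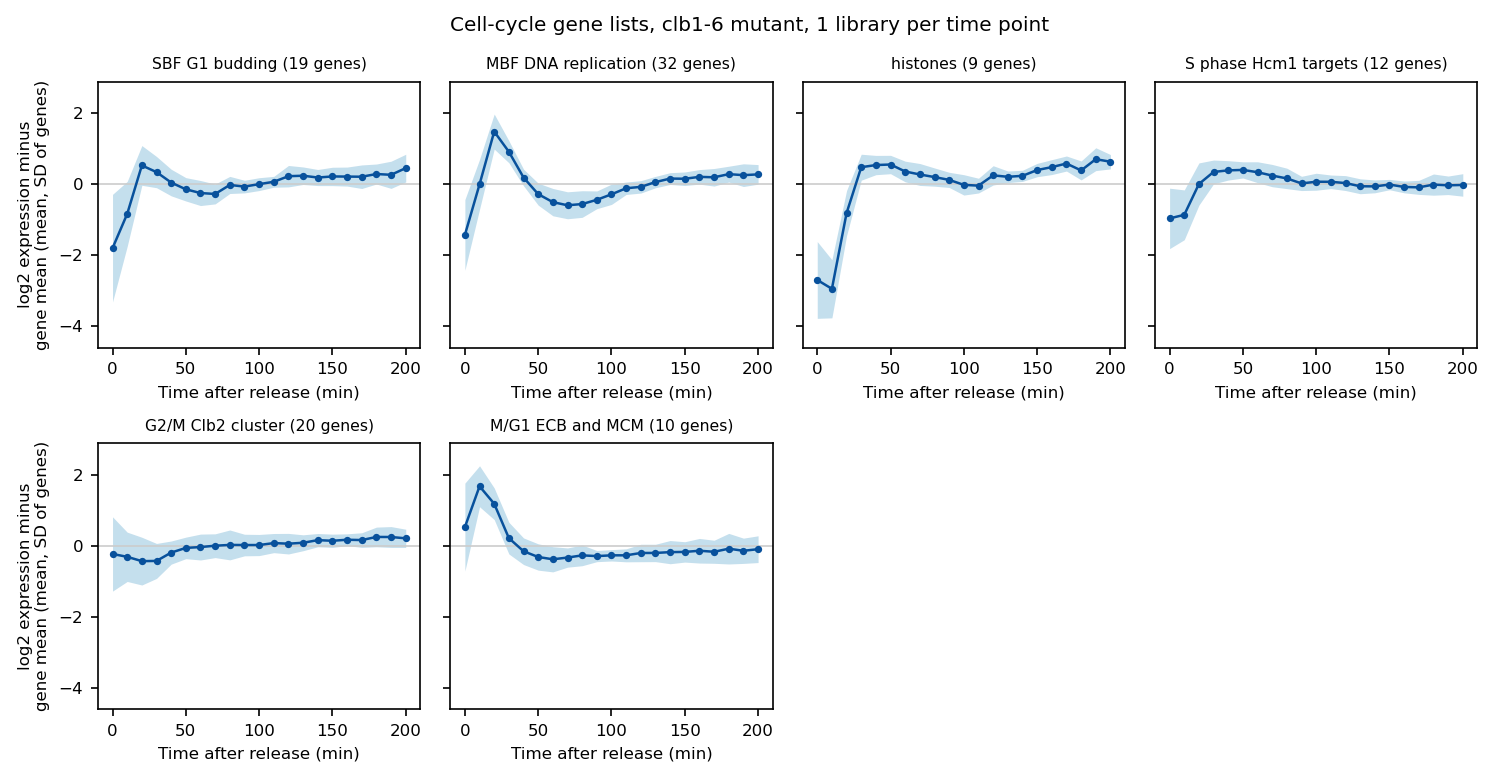
Mean log2 expression of each cell-cycle list relative to its genes' means (line, 1 point per library) and SD over genes (band) against time in min. MBF genes peaked at 1.49 at 20 min, fell to -0.59 at 70 min and stood at 0.28 at 200 min, and the Clb2 cluster showed no such early peak.

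Among the other lists, all 26 pheromone genes changed, such as the a-factor genes MFA1 (34816 FPKM at 0 min, 1752 at 200 min) and MFA2 (41687 and 1950) and the mating genes FIG1 (2627 and 91.5) and FIG2 (1743 and 89.3). Galactose genes had 8 of 8 called, with GAL1 at 102 FPKM at 200 min, and stress genes 22 of 22, with SPI1 at 937 FPKM at 0 min and 46.9 at 200 min. Without the 0 and 10 min libraries MFA1 (adjusted p = 0.0600) and SPI1 (0.220) did not pass. Called in full or nearly so were also the TCA cycle (14 of 14, SDH4 from 523 to 130 at 30 min and 270 at 200 min), cell wall integrity (7 of 7, SED1 from 5459 to 1133 at 40 min and 7727 at 200 min), glycolysis (15 of 16, ENO1 from 2525 to 65.2 at 40 min and 254 at 200 min) and glucose-repressed genes (20 of 21, HXT7 from 59.7 to 1.32 at 30 min and 10.6 at 200 min). The counts were 6 of 8 for the glucose-induced list (HXT4 from 336 to 34.8), 11 of 18 for the respiratory chain (QCR10 from 2600 to 647) and 11 of 13 for Hsf1 chaperones (SSA1 from 170 at 20 min to 764 at 80 min). Ribosomal proteins had 13 of 20 called (ASC1 from 4709 to 1123), ribosome biogenesis 9 of 26 (NIP7 from 349 to 829 at 30 min and 507 at 200 min) and Gcn4 targets 8 of 14 (LYS20 from 20.8 at 30 min to 302 at 120 min). Iron had 6 of 13 (TIS11 from 2.81 at 60 min to 69.5 at 200 min), ergosterol 11 of 17 (ERG24 from 742 to 181), sulfur 10 of 18 (MET6 from 144 at 20 min to 642 at 40 min), phosphate 4 of 12 (PHO84 from 3 to 23.0 at 10 min) and DNA damage 3 of 7 (DIN7 from 8.96 to 49.5 at 60 min, adjusted p = 0.145 without the 0 min library). MAT alpha markers had 2 of 3 and meiosis genes 6 of 8. Adjusted over the list alone, the counts were the same for 28 of the 29 lists, and sulfur had 9.

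Over all loci the largest fitted ranges belonged to YKL145W-A, YKL100W-A, snR53, YJL127W-A, YHR022C-A, TOS6, snR52, TDH1, YDL240C-A and YLR264C-A, of which 8 are under 300 bp or have no annotated length. Several of these calls ended on leaving out 1 library, YKL145W-A without 0 or 20 min, snR52 without 20, 40, 50 or 90 min, and YLR264C-A without any 1 of 0, 10, 20, 90 and 110 to 200 min (adjusted p = 0.0551 to 0.156), and YDL240C-A did not pass without both 0 and 10 min (0.0833). TOS6 rose from 88.0 FPKM at 0 min to 8201 at 200 min (fitted range 6.5, adjusted p = 2.07e-08). TDH1, a glyceraldehyde-3-phosphate dehydrogenase gene, fell from 1360 to 23.8 at 100 min (fitted range 5.95, adjusted p = 5.12e-11). Among genes of at least 300 bp they were followed by HHF1 (5.76), ENO1 (5.75), HTA2 (5.62), CLB6 (5.53), HTB2 (5.37), HXT7 (5.32), SPI1 (5.30) and the cell-wall gene HPF1 (4.72).

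The order of the early peaks differed between lists. Called members had their highest value up to 100 min at a mean of 10 min for the ECB and MCM list (8 genes), 21 min for MBF (30 genes), 35 min for SBF (18 genes), 38.9 min for Hcm1 targets (9 genes) and 46.7 min for histones (9 genes). MBF genes peaked 25.7 min before histones (two-sided permutation test across genes, adjusted p = 0.00021 over 21 pairs of lists), 17.9 min before Hcm1 targets (adjusted p = 0.00037) and 11 min after the ECB and MCM list (adjusted p = 0.00028). They peaked 14 min before SBF genes (adjusted p = 0.0400) and 31.1 min before the Clb2 cluster (adjusted p = 0.00290). The median time was 20 min in both MBF and SBF (upper quartile 37.5 min in SBF), so a minority of SBF genes carried that difference, and the times of the Clb2 cluster had a lower quartile of 0 min and a median of 70 min, with no common peak. By the permutation test SBF genes were not told apart from histones (adjusted p = 0.440) or from Hcm1 targets (adjusted p = 0.810). Nor were they from the ECB and MCM list (adjusted p = 0.063) or the Clb2 cluster (adjusted p = 0.35). Hcm1 targets were not told apart from histones either (adjusted p = 0.44). This test was chosen after the data were seen, since the planned one on fitted peak times had at least 3 periodic members only in MBF.

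Whether genes rise and fall repeatedly in these libraries was asked with fits of an oscillation from 20 min on. The list most enriched in periodic calls was that of DNA replication genes under MBF, with 15 of the 82 loci called. The period had been chosen on the 7 cell-cycle lists, MBF included, so its test was not independent of that choice. MBF had 15 of 32 members called at 130 min (odds ratio 79.6, Fisher's exact test, adjusted p = 2.41e-19), among them POL30 (amplitude 2), RNR1 (1.93), the silencing gene SPT21 (1.65) and the thymidylate synthase gene CDC21 (1.51), all falling from 20 min to a low between 60 and 80 min and higher again by 200 min. CDC21 went from 139 FPKM at 20 min to 18 at 80 min and 64.3 at 200 min, and did not pass with a cubic trend (adjusted p = 0.0514). The fitted peaks of the 15 genes had a median of 132 min, as fitted times under 20 min were moved on by 1 period of 130 min. The mean of the MBF list was 0.07 at 130 min against 1.49 at 20 min (log2, relative to each gene's mean). So 132 min was not a time of highest values. No other list passed with the minimum amplitude, and that result rests on the minimum. By adjusted p alone, 1419 of 6194 loci passed, with 31 of 32 in MBF, 16 of 19 in SBF, 12 of 13 Hsf1 chaperones and 11 of 17 ergosterol genes. Glycolysis had 1 of 16 and ribosomal proteins 1 of 20. The ECB and MCM list had 2 of 10 (SWI4 at 1.31 and CDC6 at 1.22, adjusted p = 0.106). The lists with 1 called member were SBF (YOX1, 1.07), histones (HHF1, 1.44), the Clb2 cluster (SUR7, 1.22), cell wall integrity (PST1, 1.16), glycolysis (TDH1, 1.24), iron (TIS11, 1.45) and the cyclin genes (CLB6, 2.06), with adjusted p between 0.646 and 0.680 by Fisher's exact test. Without the 20 min library YOX1 (adjusted p = 0.105), HHF1 (0.106) and SUR7 (0.0561) did not pass by limma, nor did HHF1 without 50 min (0.0624) or 60 min (0.0554). With all 21 libraries RNR1 (0.105), SPT21 (0.0960), SWI4 (0.142), CDC6 (0.127) and YOX1 (0.789) did not pass, and from 40 min on CDC6 (0.173), YOX1 (0.283), HHF1 (0.244), SUR7 (0.380) and TDH1 (0.276) did not. A linear trend ended the calls of CDC6 (0.0581), YOX1 (0.282), HHF1 (0.149), SUR7 (0.0649) and TDH1 (0.208). Adjusted over the list alone, these counts were the same for all 29 lists.

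The period itself was not resolved by this course. The best value on the planned grid was its upper end of 130 min (54.2% of variance explained in the 7 cell-cycle lists), and extending the grid to 200 min gave 200 min (61.2%). Between 50 and 90 min no gene passed the adjusted p by limma, with 53 to 570 genes at an unadjusted p under 0.05. At 130 min 1419 of 6194 loci passed adjusted p (2261 unadjusted), and 82 of them had an amplitude of at least 1. Restricting the fit to 40 min and later left 34, and without the 20 min library there were 57. For RNR1, POL30, SPT21 and CDC21 the fit followed a high value at 20 min, a low and a later rise, while YLR413W, OLE1 and TIR3, named below, were highest at 80 min.

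Over all loci the rule named YLR163W-A, YJR140W-A, YMR307C-A, YLR413W (amplitude 2.18), CLB6, POL30, RNR1, the acetaldehyde dehydrogenase gene ALD6 (1.87), the transcription factor gene MSA2 (1.83) and YBR071W (1.78). YLR413W was at 50.8 FPKM at 20 min, 475 at 80 min and 34.8 at 200 min. On leaving out 1 library YLR163W-A did not pass without 20 min (adjusted p = 0.0745), nor YJR140W-A (0.0993) and YMR307C-A (0.169) without 200 min. From 20 min, where the fit starts, ALD6 went from 173 FPKM to 67.2 at its lowest and 336 at 200 min. MSA2 went from 81.5 at 20 min to 6.48 and then 44.0. Both were highest at 10 min, outside the fit, at 1317 and 97.6. Among genes of at least 300 bp the fatty acid desaturase gene OLE1 (1.77), SPT21 and the cell-wall gene TIR3 (1.55; adjusted p = 0.0800 with a cubic trend) came next.

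Whether the oscillation changed along the course was tested over the same libraries. At 130 min, a period this course did not resolve, the products of cosine and sine with time passed for 252 of 6194 loci (1074 at an unadjusted p under 0.05). Adjusted over the 82 periodic loci alone, they passed for 46. Among the 252 were the MBF genes RNR1 (adjusted p = 0.00760), POL30 (0.00401), SPT21 (0.00733) and CDC21 (0.0412) by limma. CLB6 did not pass (adjusted p = 0.566). The count of 252 rests on single libraries, with 40 without the 20 min library, 91 without 40 min, 128 without 200 min, 151 to 165 without 50, 90, 130, 150, 160 or 170 min, and 325 without 120 min.

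**Figure D4:**
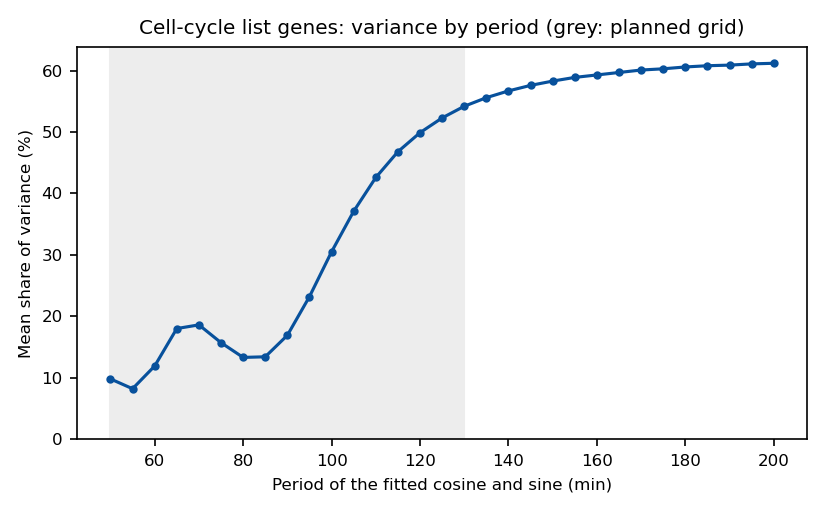
Mean share of variance in percent explained by a cosine and a sine over the genes of the 7 cell-cycle lists, against the period in min, with the planned grid shaded. The share was 54.2% at 130 min and rose on to 61.2% at 200 min, with a smaller local maximum of 18.6% at 70 min.

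Slow change along the course was asked by comparing the late window (110 to 200 min) with the early window (10 to 100 min), 10 libraries each. By camera at the preset correlation, ribosome and mating lists were lower late, and the iron, Gcn4 and cell wall integrity lists were higher. Each of these list calls was lost on estimating the correlation between genes (adjusted p = 0.618 with an estimated correlation). By limma 3013 of 6194 loci differed, 1604 higher and 1409 lower, and of these 149 were at least 2-fold higher and 42 at least 2-fold lower. Among the 5442 genes over 300 bp these counts were 73 and 33. Rescaling each library to one sum of FPKM moved the median of all genes from 0.04 to 0.24 and the calls to 2784 higher and 529 lower, with 2133 genes shared. The split into higher and lower genes thus depends on scaling. The member counts and medians of the lists below depend on it too, while camera compares each list with all other genes.

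All 26 ribosome biogenesis genes fell (median -0.45, camera adjusted p = 2.54e-14), among them DBP3 (148 ± 20.4 FPKM early, 91.5 ± 5.04 late, SD, n = 10 libraries each), RLP7 (-0.64), UTP4 (-0.63) and DBP9 (-0.58). Ribosomal protein genes fell in 17 of 20 cases and 3 did not pass (median -0.55, camera adjusted p = 3.73e-07), with ASC1 (2245 ± 710 to 1044 ± 270), RPS13 (-0.86), RPL39 (-0.80) and RPL30 (-0.69). Pheromone genes fell in 25 of 26 cases (median -0.94, camera adjusted p = 3.89e-08), including the a-factor genes MFA2 (9172 ± 6236 to 3108 ± 1625) and MFA1 (-1.40), FIG1 (-1.35) and PRM6 (-1.11), while PRM5, a gene also listed under cell wall integrity, rose (+0.43). For all 3 lists the adjusted p = 0.618 with an estimated correlation.

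Galactose genes fell in 6 of 8 cases (median -0.58, camera adjusted p = 0.0208; adjusted p = 0.692 with an estimated correlation), with GAL10 at -1.08, GAL1 at -1.07 (258 ± 172 to 107 ± 13.7 FPKM), GAL7 at -1 and GAL2 at -0.94. Respiratory chain genes fell in 13 of 18 cases (median -0.35, camera adjusted p = 0.000223; adjusted p = 0.618 with an estimated correlation), led by the complex III gene QCR10 (-0.83), COX7 (-0.73) and COX4 (-0.69). Sulfur and methionine genes fell in 8 of 18 cases, with STR3 at -1.18, the methionine synthase gene MET6 at -1.14 (354 ± 203 to 144 ± 50.4 FPKM), MET14 at -1.04 and MET2 at -1 (median -0.47, camera adjusted p = 0.0147; adjusted p = 0.702 with an estimated correlation). Ergosterol genes fell in 9 of 17 cases and rose in 2, with the sterol methyl oxidase gene ERG25 at -0.96 (1060 ± 96.3 to 560.0 ± 156 FPKM), HMG1 at -0.84 and ERG11 at -0.72 (median -0.25, camera adjusted p = 0.0320; adjusted p = 0.702 with an estimated correlation).

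Iron genes rose in 9 of 13 cases (median +0.54, camera adjusted p = 0.000389; adjusted p = 0.618 with an estimated correlation). They included TIS11 (YLR136C, chromosome XII, 415801 to 416658), which encodes a protein that binds mRNAs in iron shortage, from 6.83 ± 3.75 to 42.6 ± 14.1 FPKM (+2.54 ± 0.25, SE), the reductase gene FRE1 (+1.39), FIT2 (+1.06) and HMX1 (+0.95). Amino acid genes under Gcn4 rose in 11 of 14 cases and ARG8 fell (median +0.62, camera adjusted p = 0.00225; adjusted p = 0.618 with an estimated correlation), with LYS9 at +1.60 (143 ± 85.4 to 381 ± 51.8 FPKM), LYS1 at +1.52, ARG1 at +1.44 and LYS20 at +1.36. LYS20 (+0.60, adjusted p = 0.164) did not pass with windows of 40 to 110 and 130 to 200 min, nor ARG8 (-0.08, adjusted p = 0.429) with libraries rescaled to one sum. ARG4, a disruption marker, rose too (+1.11). Cell wall integrity genes rose in 6 of 7 cases, such as SED1 (+1.27), CWP1 (+1.24), the kinase gene SLT2 (+0.87) and PST1 (+0.82), with a list median of +0.82 (camera adjusted p = 0.00939; adjusted p = 0.618 with an estimated correlation).

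Stress genes under Msn2/4 rose in 14 of 22 cases, among them the trehalose synthesis genes TSL1 (12.1 ± 3.4 to 30.7 ± 7.47 FPKM) and TPS1 (+0.83), HSP42 (+1.04) and the catalase gene CTT1 (+0.95), with 8 that did not pass (median +0.59, camera adjusted p = 0.00254; adjusted p = 0.692 with an estimated correlation). TCA cycle genes rose in 7 of 14 cases, with ACO1 at +0.90, IDH2 at +0.84 and IDH1 at +0.79 (median +0.25, camera adjusted p = 0.0207; adjusted p = 0.702 with an estimated correlation). In the Clb2 cluster 10 of 20 genes rose and 10 did not pass (median +0.33, camera adjusted p = 0.0426; adjusted p = 0.618 with an estimated correlation), with the chitin synthase gene CHS2 at +0.73 (19.6 ± 7.20 to 31.2 ± 2.07 FPKM), the deacetylase gene HST3 at +0.63 and BUD4 at +0.54, which did not pass without 20, 30, 160 or 180 min (adjusted p = 0.0501 to 0.0661). The camera call of the list ended with windows of 40 to 110 and 130 to 200 min (adjusted p = 0.136), without the 110, 120, 180 and 190 min libraries (adjusted p = 0.0551) and with libraries rescaled to one sum (adjusted p = 0.0514). BUD4 stood at +0.14 with those windows (limma, adjusted p = 0.0541) and did not pass without those libraries either (0.13).

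The remaining cell-cycle lists did not pass camera between the windows. SBF genes rose in 7 of 19 cases, with CRH1 (+1.27) and SVS1 (+0.96), and PCL2 fell (camera adjusted p = 0.109). RFA2 (+0.69) was the only 1 of 32 MBF genes that passed, and HHT1 (+0.96) the only 1 of 9 histone genes. Of 12 Hcm1 targets BIM1 (-0.55) and FKH2 (-0.32) fell, and of the ECB and MCM list FAR1 (-1.10). Camera adjusted p for these last 4 lists lay between 0.218 and 0.605. Of the cyclin genes CLB1 (-0.70) and CLB3 (-0.15) fell, the latter turning to 0.06 with libraries rescaled to one sum (adjusted p = 0.526) and not passing without any 1 of 20, 40, 50, 80, 140, 160, 170 and 190 min (0.0510 to 0.0705). With that rescaling PCL2 (adjusted p = 0.0725) and FKH2 (0.332) did not pass.

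Lists of metabolism that did not pass camera were glucose-repressed genes, with 8 of 20 higher, led by GLK1 (+1.13; camera adjusted p = 0.139), and glycolysis, with 4 of 16 higher, led by GPM1 (+0.84), and 1 lower (0.351). Hexose transporters HXT1 (-0.82), HXT4 (-0.73) and HXT3 (-0.60) fell while the repressor gene MIG1 rose (+0.56; list adjusted p = 0.283 by camera), HXT4 (adjusted p = 0.105) and HXT3 (0.0608) not passing with libraries rescaled to one sum. Chaperones had 1 of 13 higher (STI1, +0.66, but +0.24 with adjusted p = 0.172 for windows of 40 to 110 and 130 to 200 min, and 0.0606 without the 110, 120, 180 and 190 min libraries), DNA damage genes 2 of 7 higher, led by MAG1 (+0.96), and 1 lower, and phosphate genes 2 of 12 in each direction, led by PHM6 (-1.27). For phosphate genes the median (+0.10) and the mean (-0.07) differed in sign. MAT alpha markers had 2 of 3 higher (STE3, +0.60) and meiosis genes 3 of 8 higher (DMC1, +1.27; IME2, +0.82) and 1 lower. Adjusted over the list alone the counts were the same for 23 of 29 lists, and the others were glucose-repressed 6 higher, glycolysis 1 higher, respiratory chain 14 lower, TCA cycle 8 higher, chaperones 0 and phosphate 1 in each direction. With an estimated correlation no list passed, 0 of the 13 that camera called at the preset correlation, whereas fry called 17 lists, 10 higher and 7 lower. Higher by fry but not called by camera were SBF (fry adjusted p = 0.0408), DNA damage (0.0275), MAT alpha (0.00259) and meiosis genes (7.76e-06).

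Over all loci the rule named as largest rises YHR022C-A, snR53, YJL127W-A, YNL103W-A, YOR231C-A, snR52, YPR092W, TIS11, GRE2 and YDR371C-A, of which 8 are under 300 bp or have no annotated length. YHR022C-A was listed at 0 in all 10 early libraries, and snR52 did not pass without any 1 of 10, 20, 40, 50, 60 and 170 min (adjusted p = 0.0510 to 0.0641). The largest falls were YGL204C (-1.55), YLR413W (-1.54), snR87, MFA2, MFA1, YGL101W (-1.38), FIG1, OLE1 (-1.34), snR33 and the adenine deaminase gene AAH1 (-1.31). GRE2, a reductase gene, rose from 34.6 ± 22.4 to 204 ± 92.8 FPKM (+2.53 ± 0.32, SE, adjusted p = 7.53e-06). Among genes of at least 300 bp the rises that followed TIS11 and GRE2 were HPF1 (+2.39), the sulfiredoxin gene SRX1 (+2.19), YBR071W (+1.98), YLR053C (+1.97), the peroxiredoxin gene PRX1 (+1.95), the protease gene YPS3 (+1.88), BOP2 (+1.88) and the peroxiredoxin gene AHP1 (+1.79).

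**Figure D5:**
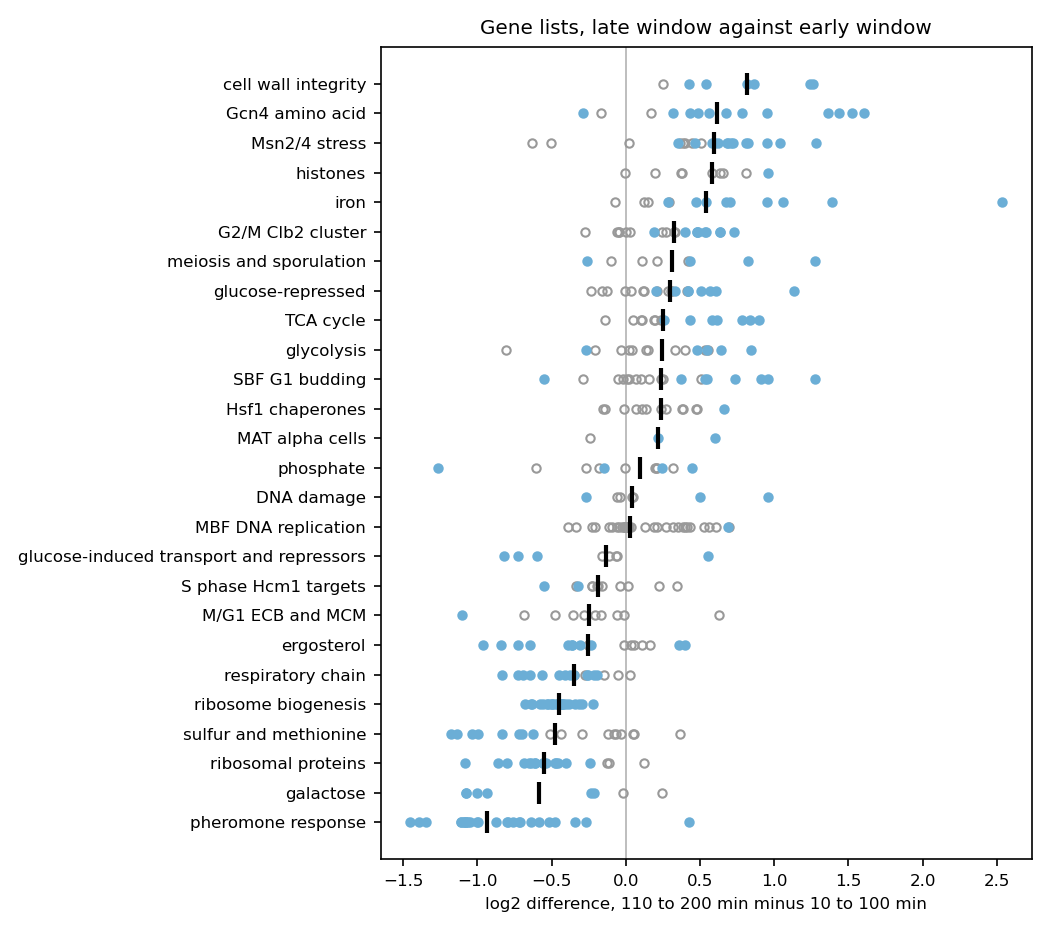
Difference in mean log2 expression between the late window (110 to 200 min) and the early window (10 to 100 min) for each list member, filled where adjusted p was under 0.05, with the list median as a bar. Pheromone genes had a median of -0.94 and cell wall integrity genes of 0.82.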

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

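All tests of explanations in this part were chosen after the result was seen, except the counts of other splits of the libraries, which were set before it.

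Histone and Hcm1 genes were lowest of the early window at 10 min, close to their means of -2.69 and -0.96 at 0 min, which lies outside both windows. In each window of 10 libraries the gap of the highest or lowest library to its nearest neighbour was divided by the range of the window, and gaps above the 95% critical value of Dixon's test were kept. Of 80 groups examined 10 had such a library, 9 of them given here. Chance gives about 1 in 20 only for independent values. Successive libraries of 1 course are not independent, so the 10 cannot be read as an excess over chance. The mean of the histone list stood at -2.94 at 10 min, with the nearest library of the window at -0.81 (gap 0.609 of the range), and that of Hcm1 targets at -0.86 against 0.01 (0.686). At 10 min the highest means belonged to glucose-repressed genes (0.719), cell wall integrity (0.573), Msn2/4 stress genes (0.541), the glucose-induced list (0.507) and galactose genes (0.469). The others were cell wall integrity lowest at 110 min (0.55) and the median of genes over 4000 bp highest at 100 min (0.476). In 7 of the 10 the library was that of 10 min, the first after release, and no explanation was tested for any of them.

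CLB6 and CLB5 rose after release in libraries labelled as the clb1-6 mutant. From 0 min to the mean of 20 and 30 min CLB6 changed by +5.81 and CLB5 by +1.66 on the log2 scale, while CLB1 changed by -0.42. Reads of the CLB1 transcript assigned to both genes would need them to follow CLB1, and the smaller of their changes exceeded that of CLB1 by 2.08, which argues against it. Cells that keep all 6 genes would bring CLB4 reads, and the highest CLB4 value was 0 FPKM. Transcripts from parts of both loci left in place could give these values, since 30 of 32 MBF genes also had their highest early value at 20 or 30 min, but values per gene do not show the position of reads, so this stays open.

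Glycolytic genes stepped up together from 70 to 80 min and from 110 to 120 min. All 16 members were higher at each step, with medians of +0.78 and +0.69, and the list fell back by -0.71 from 80 to 100 min and by -0.50 from 120 to 140 min. Random lists matched on gene length and abundance stepped up as well, with medians of +0.25 and +0.24, so part of the step goes with these. Both list medians were at percentile 100 of the matched lists, but the matching used broad bins, so it cannot exclude length and abundance for the rest. The libraries also differed otherwise. The 10 most abundant loci took 19.2% of the sum at 70 min and 12.4% at 80 min. Relative to each gene's median (log2), genes up to 300 bp went from 0.21 to -0.14 at the first step and from -0.24 to 0.11 at the second. A technical difference between these libraries was not tested. A factor per library moves the list and its matched lists alike, and the smaller difference between them was 0.449, which argues against scaling as the whole cause. The size of the second step does depend on it, as rescaling to one sum gave +0.91 with 16 of 16 higher for the first and +0.33 with 13 of 16 higher for the second. Cell wall integrity (+0.27 and +0.50), marker genes (+0.44 and +0.38), stress genes (+0.45 and +0.25), the TCA cycle (+0.26 and +0.36), Gcn4 targets (+0.42 and +0.18), ribosomal proteins (+0.17 and +0.37), iron (+0.28 and +0.23), glucose-repressed (+0.23 and +0.24) and phosphate genes (+0.23 and +0.22) moved the same way with smaller medians, and no biological explanation was tested.

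Other splits of the 20 libraries of the late and early windows were counted with 100 splits, the real one included. For genes, 1 of 100 splits gave as many, the real one with 3013, and the highest other gave 0. Libraries of 1 course in time order cannot be exchanged freely, and random splits mix early with late time points, so these splits do not exclude chance for that count. For gene lists, 32 of 100 splits gave at least the real 13, with 20 the highest, so chance is not excluded for the number of lists. Windows of 10 successive libraries starting elsewhere on the course, chosen after the data were seen, gave 40 genes (start at 70 min) to 2932 (start at 20 min) and 7 to 14 lists.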

How the results depend on the processing

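Chosen after the result was seen were the fits without the 110, 120, 180 and 190 min libraries, from 60 min with a linear trend, on genes of at least 300 bp, with the period grid to 200 min, and one-sum scaling of list results. Those 4 libraries lie in the late window. Relative to each gene's median (log2), their genes up to 300 bp stood at -0.24, 0.11, -0.20 and 0.30 in time order. Genes over 4000 bp stood at 0.21, -0.03, 0.15 and -0.02. At 70 min the shorter genes stood at 0.21 as well. A shift with gene length may thus enter late-window results. Without those 4 libraries 2510 genes differed between the windows, 2465 of them among the 3013. No paired analysis was possible because there is 1 library per time point and no second group.

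LEU2 and TRP1 no longer passed for change over time without the 0 and 10 min libraries (adjusted p = 0.391 and 0.847), nor did CLB5 (0.113), RNR1 (0.214), POL30 (0.0552) and YLR264C-A (0.313) with a spline of 4 degrees of freedom. For oscillation, a cubic trend ended the calls of CDC21 (adjusted p = 0.0514), SUR7 (0.273) and TIR3 (0.0800), a linear trend those of CDC6 (0.0581), YOX1 (0.282), HHF1 (0.149), SUR7 (0.0649) and TDH1 (0.208), each gene's own best period those of CDC6 (0.0524), YOX1 (0.168), HHF1 (0.422) and SUR7 (0.131), and a period 15 min shorter that of HHF1 (0.0835). YLR163W-A, YJR140W-A and YMR307C-A each lost theirs with a cubic trend and with their own best period (0.0733 to 0.382). Genes changing over time (2775) became 5127 with no minimum range, 772 with a minimum range of 2 and 1734 without the 0 and 10 min libraries, and leaving out 1 library gave 1910 (0 min) to 2842 (120 min). Periodic genes (82) became 124 with libraries rescaled to one sum, 141 with a period 15 min longer, 307 with all 21 libraries, 34 from 40 min, 1419 with no minimum amplitude, 474 with a minimum of 0.5, 142 without the 110, 120, 180 and 190 min libraries and 20 from 60 min with a linear trend. Leaving out 1 library gave 57 (20 min) to 106 (120 min). The best period became 200 min on the longer grid. Genes whose oscillation changed (252) became 119 with one sum, 398 and 165 with a period 15 min shorter and longer, and 130 without those 4 libraries, with 40 (20 min) to 325 (120 min) on leaving out 1 library. Lists that differed from other genes in periodic calls (1) became 7 by adjusted p alone and 2 with a period 15 min longer.

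Between the windows, one-sum scaling gave 2784 genes higher and 529 lower in place of 1604 and 1409. A minimum change of 1 left 191 genes, 149 higher and 42 lower. Leaving out 1 library gave 2769 (40 min) to 3398 (10 min) genes, 1466 (200 min) to 1828 (10 min) higher and 1300 (40 min) to 1570 (10 min) lower. Of the 13 lists camera called, an estimated correlation left 0, with 0 higher and 0 lower, and fry called 17 lists, 10 higher and 7 lower. One-sum scaling kept the number at 13, but the Clb2 cluster (median 0.53) no longer passed and the ECB and MCM list (-0.05) did. It also turned the medians of Hcm1 targets to 0.02 and glucose-induced genes to 0.07, none of them called, and the difference of CLB3 from -0.15 to 0.057. With windows of 40 to 110 and 130 to 200 min the medians of the ECB and MCM list (0.03) and of chaperones (-0.05) changed sign, neither of them called. Outside the counts above, named genes were compared by adjusted p alone, so a fall under the minimum range or amplitude was not counted. Named genes and lists stayed on the same side of 0.05, or for release medians within 1 SD, in 6539 comparisons with an alternative. They no longer passed in 159, newly passed in 15 and moved by more than 1 SD in 37. In 2, CLB3 above and Gcn4 targets below, a value that was called or beyond its SD changed sign, and sign changes of other medians are counted among the 6539 or the 37.

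With the mean of 10 and 20 min in place of 20 to 40 min, the release medians were -1.30 for pheromone genes and -1.64 for galactose genes, while that of Gcn4 targets turned from -0.26 to 0.15 and that of the ECB and MCM list from -0.39 to 0.69. Among values near 0, one-sum scaling gave 0.18 for the Clb2 cluster and 0.14 for MAT alpha markers in place of 0.00 and -0.03. Thresholds, numbers of libraries and time points change these counts by construction, and the cause of the other changes was not tested. Depth limits values near the minimum of 1 FPKM. By the bounded estimate given above, these rest on about 15.2 to 22.5 fragments in a gene of 1000 bp and on fewer in shorter loci.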

Other observations

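The test in the last paragraph was chosen only after the result was seen, and the other values were noticed in the data and carry no test.

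Of the 18 sulfur genes, 3 picked after their values were seen had high values between 20 and 50 min, with no test of such a pulse for them or the list. MET6 went from 626 FPKM at 10 min to 144 at 20 min, 642 at 40 min and 184 at 50 min, STR3 from 11.9 at 20 min to 103 at 30 min and 17.2 at 50 min, and MET14 from 213 at 20 min to 834 at 40 min. The chaperone genes SSA1 and HSP60, also picked, were at 764 and 685 FPKM at 80 min, from 170 and 236 at 20 min.

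SBF genes came closer to their level at 20 or 30 min at the end of the course than MBF genes. The mean of 180 to 200 min minus the higher of 20 and 30 min was -0.23 for 18 SBF genes (SD 0.753), with 7 at or above that level, and -1.27 for 30 MBF genes (SD 0.485), with 0 at or above it. The difference of 1.04 had p = 1e-05, the smallest that 100000 permutations across genes give. The list means were 0.53 (SBF) and 1.49 (MBF) at 20 min but 0.46 and 0.28 at 200 min. The difference thus went mostly with the higher early peak of MBF genes. Early maxima of SBF genes had an upper quartile of 37.5 min, so this reference missed the peak of some of them. The test therefore does not show that the lists differ in how far they return. It was found and tested on the same data, and genes of 1 culture are not independent replicates.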
